A study of Homo sapiens with 21 samples.

How the data were processed

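Transcript levels were measured with Affymetrix oligonucleotide arrays in HEK293 cells, an established human embryonic kidney line. The series held 21 arrays in 7 groups of 3: attached monolayers, attached monolayers grown with antibiotics, unstored spheroids, spheroids stored dry for 2, 4 or 6 weeks, and cells returned to attached culture for 72 hours after 2 weeks of storage. Groups came from the labels, and the replicate number came from the sample titles. The labels do not say whether a number marks a separate culture, a separate RNA sample or a repeated hybridisation, so the p-values may measure technical spread alone.

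The authors deposited a single value table with 22283 probe sets and 1 column per array. The deposited values were summarised probe set intensity on a linear scale, in whole numbers. How background was corrected, probes were summarised and arrays were scaled is not given in the sources used here. Array medians lay between 477 and 520, and the highest intensity on an array lay between 42553 and 44766, so bright transcripts met a ceiling. A group mean above 38830 was called near the ceiling, which applied to 75 genes. The number of arrays limits the precision.

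The probe annotation gave 1 gene symbol for 19064 probe sets and several for 1043. No symbol was used for 2108 probe sets, and 68 control probe sets were kept apart. Symbols were matched to the reference by gene number for 19053 probe sets, and the reference symbol was used where it differed. Intensities under the 10th percentile of the whole table, 158, were set to that floor, which applied to 8.59% to 11.1% of probe sets per array, and values were log2 transformed. No further scaling was applied. The lowest 25% of probe sets by mean log2 intensity was left out, and 16661 probe sets remained, with or without a gene symbol. Among those with 1 symbol, the probe set with the highest mean stood for its gene. This left 9844 genes, of which 3153 had more than 1 probe set that passed the filter. No genome build or coordinates were used.

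Differences were tested in R 4.3.3 with limma 3.58.1 in a single fit of all 21 arrays with 7 group means and 14 residual degrees of freedom, with moderated variances and an intensity trend. Tests were two-sided. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and a gene passed at a false discovery rate (FDR) of 5%. Errors of log2 differences are standard errors (SE) from this fit, and errors of group means are standard deviations (SD) of intensity. Of 39 gene lists fixed in advance, 38 had at least 5 measured genes and were tested with limma's camera, with a preset correlation between genes of 0.01. List p-values were adjusted over the 38 lists. The remaining list, of mitochondrially encoded transcripts, had no measured gene. The list test was repeated with a correlation estimated from the data and with limma's fry.

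The 9 comparisons, the lists and the rule for naming genes were fixed before the data were examined. The rule takes, in each comparison, the 6 largest rises and 6 largest falls among genes past 5% FDR whose groups did not overlap in any array and whose higher group mean exceeded the median of all genes. It adds the 3 members with the smallest p from each list that passed or had at least 3 members past 5% FDR. It gives 101 to 120 genes per comparison, 1030 in all. The text names 247 gene and comparison pairs, chosen after their values were seen: the largest changes, and members of the lists described. Of these, 1 pair lies outside the rule. The comparisons of recovered cells with monolayers grown without antibiotics and of 6 with 4 weeks were chosen as comparisons of their own after the data were seen, as were the genes and lists named in them.

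The spike-in transcript BioB, added at hybridisation, divided the arrays into 2 sets, called hybridisation sets here although the labels give no hybridisation date. The 12 arrays of the monolayer, spheroid, 2-week and recovered groups read 520 to 747 on its 3' probe set, and the 9 arrays of the 4-week, 6-week and antibiotic monolayer groups read 823 to 1409. The spike-in BioC did not divide them (3561 to 6488 and 2697 to 4880 on its 5' probe set), while the ratio of BioB to BioC, chosen after the data were seen, read 0.114 to 0.146 and 0.236 to 0.326. That the sets were separate runs is inferred from these controls. Each group lay within 1 set, so differences across the sets cannot be told apart from the set, and values within a set are given beside many of them.

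The alternatives were other floors and filters, the mean of a gene's probe sets, every probe set on its own, quantile normalization, centring on the array median, no intensity trend, array weights, the compared groups alone, the replicate number as a block, another control for the recovered cells, and each array left out in turn. Added after the data were seen were the subtraction of the difference between the monolayer groups, the mean of the stored groups without the 4-week arrays, and settings at the level of single lists. The monolayer difference holds antibiotics as well as set, so calls gained, lost or reversed by subtracting it may come from antibiotics. The procedure was tested on simulated data, with 200 of 9844 genes changed in each of 10 draws of the comparison of 2 weeks of storage with spheroids. It recovered 86.7% of genes changed 1.5-fold and 99.7% of genes changed 2-fold, and 5.21% of its calls were false. A list shifted by 0.5 on the log2 scale was found in 10 of 10 draws, with 0 other lists. Noise was drawn independently for each gene and no other list was shifted. These draws therefore do not show how often lists are called falsely where genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.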

Results

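The arrays measured 9844 genes in HEK293 cells grown attached, grown as spheroids in suspension for 7 days, kept as spheroids without medium in sealed flasks at room temperature, or returned to attached culture after storage. Each of the 7 groups had 3 arrays. Group values below are mean intensities ± SD (n = 3), and changes are log2 fold changes with their SE. The median SD of a gene within a group ranged from 0.10 on the log2 scale in monolayers to 0.15 in recovered cells. The 5' control probe set for 28S ribosomal RNA read 229.7 ± 5.69 in spheroids, 468 ± 54.1 after 2 weeks, 1159 ± 145 after 4 weeks and 413.7 ± 258 after 6 weeks of storage. At 6 weeks replicate 1 read 711 and the other arrays 272 and 258, all above the 225 to 236 of spheroid arrays. The middle probe set read 1800 ± 44.4 in spheroids and 2693 ± 227, 4477 ± 521 and 2960 ± 722 after 2, 4 and 6 weeks. The log2 ratio of 3' to 5' signal of ACTB was -0.18 ± 0.01 in spheroids and -0.01 ± 0.20, -0.06 ± 0.07 and -0.19 ± 0.06 after 2, 4 and 6 weeks. That of GAPDH was -0.014 ± 0.001 in spheroids and 0.102 ± 0.040 after 6 weeks, where all 3 arrays lay above all spheroid arrays. Those probe sets lay not far from the ceiling, which compresses the ratios, and no difference can pass in an exact permutation test of 3 against 3 arrays, whose smallest p is 0.1.

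**Figure D1:**
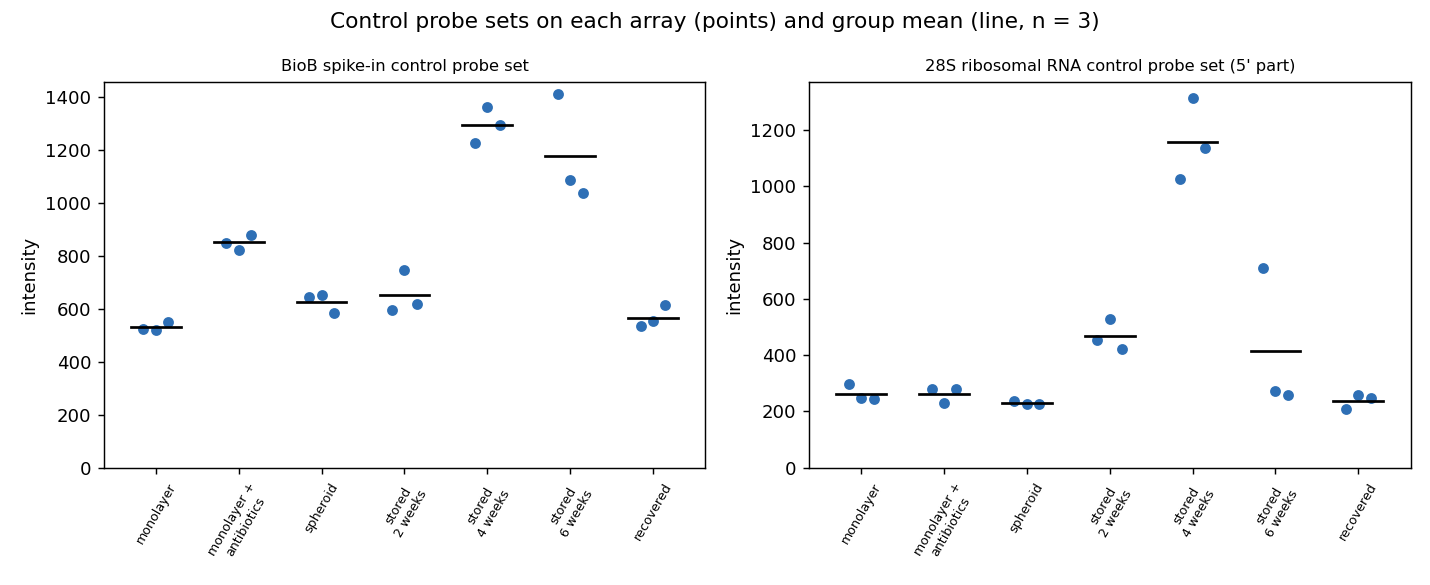
Intensity of the BioB spike-in and of 28S ribosomal RNA (5' part) control probe sets on linear axes, by group; points are arrays and lines are means of 3 arrays. BioB read 520 to 747 in 4 groups and 823 to 1409 in the other 3, and the 28S mean was highest at 4 weeks, 1159.

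Genes past 5% FDR numbered 3058 between spheroids and monolayers (1427 higher, 1631 lower), 4632 after 2 weeks of storage (2190 higher, 2442 lower, but 2548 and 2330 after centring on the array median and 2529 and 2299 after quantile normalization), 6259 after 4 weeks (3498 higher, 2761 lower) and 5204 after 6 weeks (2819 higher, 2385 lower). With the dimmer 50% of probe sets left out, more genes were lower than higher at 4 weeks (2248 higher, 2391 lower) and 6 weeks (1941 and 2078), as also with the difference between the monolayer groups subtracted (1801 and 2234 at 4 weeks, 1706 and 1851 at 6 weeks). Most of these changes were small. Over 2-fold, 322 genes differed between spheroids and monolayers, 189 of them higher in spheroids, and 959, 1272 and 831 genes differed from spheroids after 2, 4 and 6 weeks. After 4 weeks, 1113 of the 2461 dimmest genes passed as higher and only 28 of them by over 2-fold.

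**Figure D2:**
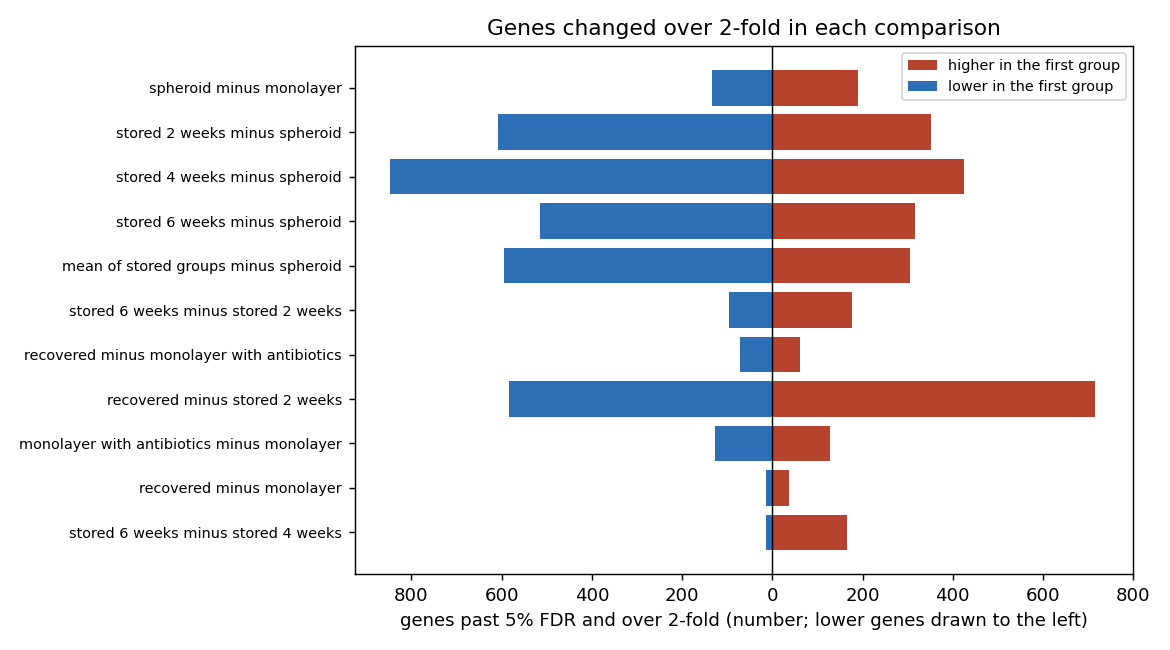
Numbers of genes past 5% FDR that changed over 2-fold in each comparison, as bars to the right for higher and to the left for lower genes. The fewest, 49, separated recovered cells from monolayers grown without antibiotics, and the most, 1299, separated recovered cells from cells stored for 2 weeks.

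The comparison of unstored spheroids with attached monolayers asked what changed with culture form, within the first hybridisation set. Spheroids had grown for 7 days and no culture time is known here for the monolayers, so time in culture may differ along with form. Spheroids had higher transcripts of stress response, immediate early and p53 target genes, and lower transcripts of mitosis, oxidative phosphorylation, proteasome and glycolysis genes. With an estimated correlation only the integrated stress response, p53 target and NF-kappaB target lists passed. GDF15 (221577_x_at), a secreted cytokine induced by cell stress, rose from 221.7 ± 19.4 to 4694 ± 761, 21-fold (4.39, SE 0.24, adjusted p = 1.19e-11). Other large rises were of ATF3 (202672_s_at; 2.93, SE 0.17) and NUPR1 (209230_s_at; 2.82, SE 0.18), both stress-induced regulators of transcription, of TNFRSF9 (207536_s_at; 2.91, SE 0.15), a receptor of the tumour necrosis factor family, and of NFKBIA (201502_s_at; 2.65, SE 0.20), the inhibitor of NF-kappaB. NHLH2 (215228_at), a transcription factor, rose by 2.66 (SE 0.12). The largest falls were of GJA1 (201667_at; -1.86, SE 0.36), the gap junction protein connexin 43, and BUB1 (209642_at; -1.84, SE 0.14), a kinase of the spindle checkpoint. The log2 changes of PDCD2, the protocadherin PCDH7, the sterol pathway enzyme ACAT2 and LYPD1 were -1.77, -1.74, -1.74 and -1.73.

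Of 38 gene lists, 17 passed, 8 upward and 9 downward. Of 23 measured genes of the amino acid and integrated stress response, 21 rose, 0 fell and 2 did not pass, with the same counts adjusted over the list alone (median 1.59, adjusted p = 9.61e-25), among them PPP1R15A (2.33, SE 0.12) and CHAC1 (2.17, SE 0.13). Among 22 p53 target genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone; median 0.58, adjusted p = 1.97e-08), with CDKN1A, an inhibitor of cyclin-dependent kinases, rising by 2.30 (SE 0.15). NF-kappaB targets rose in 10 of 24 genes and fell in 0 (12 and 1 adjusted over the list alone; adjusted p = 8.42e-05), including TNFAIP3 (1.79, SE 0.16) and CXCL8 (1.56, SE 0.20). These 3 lists also passed with an estimated correlation, at adjusted p = 0.00206, 0.00752 and 0.0376. Immediate early genes rose in 19 of 30 and fell in 0 (20 and 0 adjusted over the list alone; adjusted p = 2.37e-12), but adjusted p = 0.0557 with an estimated correlation; GADD45B rose by 2.48 (SE 0.16) and GADD45A by 2.33 (SE 0.15). Of 20 genes of the unfolded protein response, 13 rose and 2 fell, the same adjusted over the list alone (adjusted p = 5.58e-05, and adjusted p = 0.102 with an estimated correlation). The transcription factor XBP1 rose by 1.70 (SE 0.16) and the chaperone DNAJB9 rose by 1.67 (SE 0.19).

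Genes of mitosis fell in spheroids: 32 of 53 passed as lower and 0 as higher (36 and 0 adjusted over the list alone; median -0.46, adjusted p = 1.65e-11), but adjusted p = 0.0948 with an estimated correlation. The kinase AURKA fell by 1.59 (SE 0.12) and cyclin B1, CCNB1, by 1.38 (SE 0.12). Nuclear-encoded genes of oxidative phosphorylation fell in 34 of 55 and rose in 2 (36 and 3 adjusted over the list alone; adjusted p = 3.78e-10, and adjusted p = 0.276 with an estimated correlation). CYC1 fell by 0.93 (SE 0.09) and NDUFC1 fell by 0.88 (SE 0.09). The proteasome list fell in 23 of 30 genes and rose in 0 (24 and 0 adjusted over the list alone; adjusted p = 3.78e-10, and adjusted p = 0.163 with an estimated correlation). PSMA2 fell by 1.03 (SE 0.12). Glycolysis genes fell in 13 of 17 and rose in 0, the same adjusted over the list alone (adjusted p = 1.64e-06, and adjusted p = 0.0948 with an estimated correlation). PFKM fell by 1.10 (SE 0.14) and PGK1 fell by 0.90 (SE 0.12). Antioxidant enzymes fell in 10 of 18 genes and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 6.14e-05, and adjusted p = 0.0948 with an estimated correlation). GLRX fell by 1.40 (SE 0.12) and catalase, CAT, fell by 1.24 (SE 0.13). Cholesterol synthesis genes fell in 10 of 19 and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.000827, and adjusted p = 0.0557 with an estimated correlation). INSIG1 fell by 1.16 (SE 0.15) and LSS fell by 0.99 (SE 0.10). The calls of 3 weaker lists ended when single arrays were left out: cytosolic tRNA synthetases without spheroid replicate 3 or monolayer replicate 2 (adjusted p up to 0.0805), cyclin-dependent kinase inhibitors without spheroid replicate 1 or monolayer replicate 2 or 3 (up to 0.0825), and splicing factors without monolayer replicate 1 (0.0544) or after quantile normalization (0.19).

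Storage for 2 weeks was compared with unstored spheroids, within the first hybridisation set, to ask what dry storage changed. The same 3 spheroid arrays were compared with monolayers above, with opposite sign. Lists that moved one way there and the other way here may therefore owe part of this to shared arrays. Transcripts of the integrated stress response, of matrix and of lipid synthesis genes were lower after 2 weeks, and those of proteasome, splicing and mitosis genes were higher, by camera with the preset correlation and in no list with an estimated one. SLIT2 (209897_s_at), a secreted guidance protein, dropped from 13460 ± 1720 to 800.3 ± 131, 16.9-fold (-4.08, SE 0.20, adjusted p = 8.11e-13). GDF15 fell by 4.03 (SE 0.24), and DDIT4 (202887_s_at), a stress-induced inhibitor of mTORC1, fell by 3.99 (SE 0.16). GRB10 (209409_at), an adaptor of growth factor receptors, changed by -3.76 (SE 0.14), the transcription factor SOX11 by -3.14 (SE 0.25) and the zinc exporter SLC30A1 by -3.13 (SE 0.16). ZNF34 (219801_at), a zinc finger gene, rose from a mean of 353.7 to 4456, 12.6-fold (3.65, SE 0.13, adjusted p = 4.92e-15). VCPKMT, LOC100996756, ZNF226, WTAP and ATG14 rose by between 2.41 and 2.67, of which WTAP, a subunit of the RNA methylation complex, varied most between arrays (7224 ± 2510). Of these 5 genes, only WTAP had other probe sets that passed the filter, and both moved the same way.

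Of the 38 lists, 12 passed at 2 weeks, 4 upward and 8 downward, and none passed with an estimated correlation. The integrated stress response list fell in 18 of 23 genes and rose in 1 (18 and 3 adjusted over the list alone; median -1.08, adjusted p = 1.68e-07, and adjusted p = 0.139 with an estimated correlation), including CHAC1 (-2.40, SE 0.13) and the proline synthesis enzyme ALDH18A1 (-1.27, SE 0.08). Cytosolic tRNA synthetases fell in 11 of 16 and rose in 2, the same adjusted over the list alone (adjusted p = 0.000714, and adjusted p = 0.139 with an estimated correlation). AARS1 fell by 1.67 (SE 0.11) and IARS1 fell by 1.30 (SE 0.11). Fatty acid synthesis genes fell in 10 of 11, the same adjusted over the list alone (adjusted p = 5.26e-05, and adjusted p = 0.139 with an estimated correlation). ELOVL6 fell by 1.55 (SE 0.13) and SCD fell by 1.30 (SE 0.10). Cholesterol synthesis genes fell in 13 of 19 and rose in 2 (13 and 3 adjusted over the list alone; adjusted p = 0.00637, and adjusted p = 0.139 with an estimated correlation). Unfolded protein response genes fell in 11 of 20 and rose in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.00854, and adjusted p = 0.408 with an estimated correlation). HYOU1 fell by 1.32 (SE 0.11) and PDIA6 fell by 1.13 (SE 0.12). Extracellular matrix genes fell in 18 of 41 and rose in 3 (18 and 4 adjusted over the list alone; adjusted p = 0.00305, and adjusted p = 0.502 with an estimated correlation). Fibronectin, FN1, fell by 2.53 (SE 0.21) and the laminin chain LAMC1 fell by 2.14 (SE 0.17). Actin and SRF target genes fell in 15 of 31 and rose in 4 (16 and 4 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.29 with an estimated correlation). MYH10 fell by 1.81 (SE 0.16) and ACTA2 fell by 1.79 (SE 0.15).

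Among the lists higher at 2 weeks, proteasome genes rose in 24 of 30 and fell in 1, the same adjusted over the list alone (median 0.66, adjusted p = 1.68e-07, and adjusted p = 0.36 with an estimated correlation). PSMC2 rose by 1.18 (SE 0.10) and PSMB7 rose by 1.09 (SE 0.10). Splicing factors rose in 30 of 42 and fell in 5, the same adjusted over the list alone (adjusted p = 2.71e-05, and adjusted p = 0.142 with an estimated correlation). SF3A1 rose by 1.26 (SE 0.11) and SNRPC rose by 1.01 (SE 0.08). Mitosis genes rose in 29 of 53 and fell in 8 (29 and 9 adjusted over the list alone; adjusted p = 0.000232, and adjusted p = 0.502 with an estimated correlation). CENPN rose by 1.94 (SE 0.17) and NUSAP1 rose by 1.35 (SE 0.10). In the integrated stress response list, PPP1R15A, which directs dephosphorylation of eIF2-alpha, rose by 0.49 (SE 0.12), named after its value was seen as the 1 member to rise past 5% FDR over all genes. GADD45B, a stress-induced gene of the immediate early list, rose from 6928 ± 350 to 25850 ± 1040 (1.90, SE 0.16). Calls of 2 further lists ended without single arrays: oxidative phosphorylation without the 2-week replicate 2 (adjusted p = 0.0605) and after quantile normalization (0.43), and p53 targets without spheroid replicate 1 or the 2-week replicate 1 or 3 (up to 0.077).

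Spheroids stored for 4 weeks lay in the other hybridisation set from the spheroid controls, so storage and set cannot be told apart and no value within a set exists for this comparison. The largest falls were of GRB10, from 5287 ± 315 to 301.3 ± 11.1, 17.5-fold (-4.13, SE 0.14, adjusted p = 2.49e-15), of ASXL2 (218659_at), a chromatin regulator (-3.96, SE 0.14), of GDF15 (-3.91, SE 0.24) and of SLIT2 (-3.89, SE 0.20). The receptor phosphatase PTPRK fell by 3.69 (SE 0.18), and SOX11 fell by 3.50 (SE 0.25). ZNF34 read 4818 ± 1030 against 353.7 ± 15.9, 13.4-fold higher (3.75, SE 0.13). Cyclin L1, CCNL1 (220046_s_at), rose by 2.74 (SE 0.16), the ubiquitin ligase RFWD3 (218564_at) by 2.69 (SE 0.12), and ZNF226, AFG2B and VCPKMT by 2.65, 2.57 and 2.56. ASXL2 also differed by -2.16 (SE 0.14) between the unstored monolayers of the second and first sets.

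At 4 weeks 12 lists passed, 6 upward and 6 downward, and 0 passed with an estimated correlation. Genes of the integrated stress response fell in 17 of 23 and rose in 3, the same adjusted over the list alone (median -1.12, adjusted p = 1.81e-05, and adjusted p = 0.33 with an estimated correlation). The arginine transporter SLC7A1 fell by 2.22 (SE 0.14). Cytosolic tRNA synthetases fell in 12 of 16 and rose in 1, the same adjusted over the list alone (adjusted p = 0.000472, and adjusted p = 0.33 with an estimated correlation). AARS1 fell by 1.59 (SE 0.11) and SARS1 fell by 1.17 (SE 0.09). Proteasome genes rose in 24 of 30 and fell in 1, the same adjusted over the list alone (adjusted p = 1.81e-05, and adjusted p = 0.415 with an estimated correlation). PSMD2 rose by 1.27 (SE 0.09) and PSMC1 rose by 1.11 (SE 0.09). Splicing factors rose in 29 of 42 and fell in 9 (30 and 9 adjusted over the list alone; adjusted p = 0.000534, and adjusted p = 0.33 with an estimated correlation). SF3B4 rose by 1.55 (SE 0.10). Mitosis genes rose in 35 of 53 and fell in 9, the same adjusted over the list alone (adjusted p = 0.00104, and adjusted p = 0.523 with an estimated correlation). Survivin, BIRC5, rose by 2.00 (SE 0.11) and NUSAP1 rose by 1.22 (SE 0.10). Histone genes rose in 16 of 25 and fell in 1, the same adjusted over the list alone (adjusted p = 0.00603, and adjusted p = 0.33 with an estimated correlation). H3C2 rose by 1.56 (SE 0.18) and H2AC17 rose by 1.03 (SE 0.12). Immediate early genes rose in 16 of 30 and fell in 3, the same adjusted over the list alone (adjusted p = 0.0175, and adjusted p = 0.541 with an estimated correlation). FOS rose by 2.38 (SE 0.18) and GADD45B rose by 1.60 (SE 0.16).

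Unfolded protein response genes fell at 4 weeks in 11 of 20 and rose in 4, the same adjusted over the list alone (adjusted p = 0.0207, and adjusted p = 0.415 with an estimated correlation). HYOU1 fell by 1.32 (SE 0.11). Extracellular matrix genes fell in 17 of 41 and rose in 4, the same adjusted over the list alone (adjusted p = 0.0433, and adjusted p = 0.541 with an estimated correlation). SERPINE2 fell by 2.30 (SE 0.11) and COL4A5 fell by 2.14 (SE 0.15). Without spheroid replicate 3 the matrix list did not pass (0.0531). The list of 13 leukocyte markers, genes this kidney line would not be thought to use, had 10 members higher and 0 lower, the same adjusted over the list alone (median 0.43, adjusted p = 0.0106, and adjusted p = 0.415 with an estimated correlation). Its members were dim, as in CD14, which read 475 ± 67.9 against 235.3 ± 4.73. Bacillus control probe sets, to which no cell transcript binds, also read higher at 4 weeks than in spheroids, by a median of 0.13 (95% interval 0.06 to 0.20, from resampling probe sets), less than the list. With the difference between the monolayer groups of the sets subtracted, leukocyte markers (adjusted p = 0.119), immediate early genes (0.0581) and fatty acid synthesis genes (0.176) no longer passed at 4 weeks. GADD45B then moved from 1.60 to 0.54 (adjusted p = 0.0599). Passing as well with this subtraction were oxidative phosphorylation (0.000342), nucleolar (0.00196) and heat shock genes (0.0235), higher, and p53 targets (0.00649) and integrins (0.0354), lower. The monolayer difference ran against the storage change in the integrated stress, unfolded protein, mitosis, proteasome and splicing lists, so subtraction could only enlarge their changes.

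After 6 weeks, again in the other set from the controls, ZNF34 remained higher at 2920 ± 178 (3.04, SE 0.13). PSPC1 (218371_s_at), a protein of nuclear paraspeckles, rose by 2.99 (SE 0.18), FOS (209189_at) by 2.85 (SE 0.18), from 1541 ± 63.6 to 11270 ± 2200, and the kinase SGK1 (201739_at) by 2.68 (SE 0.16). RFWD3 and WTAP rose by 2.50 and 2.47. The largest falls were of SOX11 (-3.16, SE 0.25), DDIT4 (-2.98, SE 0.16), GDF15 (-2.98, SE 0.24), GRB10 (-2.87, SE 0.14), the channel subunit LRRC8D (-2.78, SE 0.11) and NIBAN1 (-2.67, SE 0.16). The immediate early genes FOSB and IER2 read 2177 ± 299 and 35960 ± 4320 against 610.7 ± 97.1 and 17540 ± 236.

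Of the 12 lists past 5% FDR at 6 weeks, 5 were higher and 7 lower, and 0 passed with an estimated correlation. The integrated stress response fell in 18 of 23 genes and rose in 2, the same adjusted over the list alone (median -1.49, adjusted p = 1.81e-09, and adjusted p = 0.0957 with an estimated correlation). SLC7A1 fell by 2.49 (SE 0.14) and the serine synthesis enzyme PSAT1 fell by 2.19 (SE 0.15). Cytosolic tRNA synthetases fell in 11 of 16 and rose in 1, the same adjusted over the list alone (adjusted p = 5.16e-05, and adjusted p = 0.0957 with an estimated correlation). SARS1 fell by 1.14 (SE 0.09) and TARS1 fell by 1.07 (SE 0.09). The unfolded protein response fell in 11 of 20 and rose in 2, the same adjusted over the list alone (adjusted p = 0.00199, and adjusted p = 0.333 with an estimated correlation). XBP1 fell by 1.53 (SE 0.16) and PDIA6 fell by 1.21 (SE 0.12). Extracellular matrix genes fell in 18 of 41 and rose in 4, the same adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.449 with an estimated correlation). Proteasome genes rose in 22 of 30 and fell in 1, the same adjusted over the list alone (adjusted p = 3.65e-05, and adjusted p = 0.452 with an estimated correlation). PSMD2 rose by 1.39 (SE 0.09). Splicing factors rose in 27 of 42 and fell in 3 (28 and 4 adjusted over the list alone; adjusted p = 8.55e-05, and adjusted p = 0.208 with an estimated correlation). SF3B4 rose by 1.54 (SE 0.10). Histone genes rose in 14 of 25 and fell in 1, the same adjusted over the list alone (adjusted p = 0.000322, and adjusted p = 0.146 with an estimated correlation). H2BC9 rose by 1.78 (SE 0.20) and H2BC6 rose by 1.76 (SE 0.15).

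Fatty acid synthesis genes fell at 6 weeks in 9 of 11 and rose in 0, the same adjusted over the list alone (adjusted p = 7.1e-05, and adjusted p = 0.146 with an estimated correlation). ACLY fell by 1.43 (SE 0.14) and SCD fell by 1.09 (SE 0.10). With the difference between the monolayer groups subtracted, this list (adjusted p = 0.14), immediate early genes (0.074), leukocyte markers (0.279), glycolysis (0.541) and cholesterol synthesis (0.321) did not pass, and SCD moved to 0.05. Other lists passed only with the subtraction: heat shock genes, whose median moved from 0.173 to 0.918 (1.11e-05), mitosis genes, from 0.187 to 0.725 (2.07e-09), nucleolar genes (0.00111), oxidative phosphorylation (0.0317) and, as lower, p53 targets (0.0317). The subtracted difference includes any effect of antibiotics, so these calls may come from the subtraction and not from storage. The cholesterol list also did not pass after quantile normalization (0.0545).

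**Figure D3:**
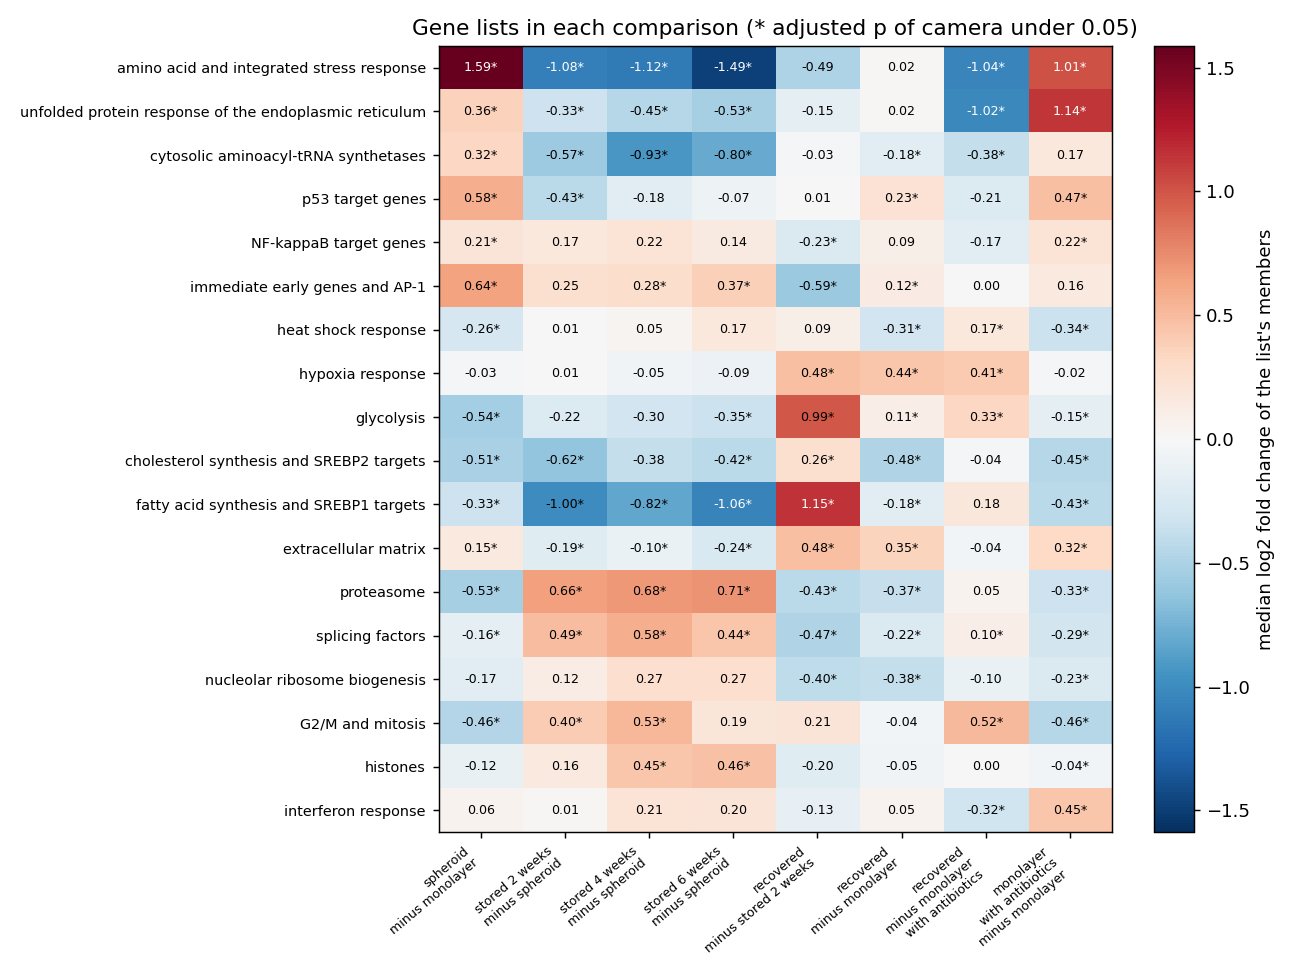
Median log2 fold change of the measured members of 18 gene lists in 8 comparisons, as a colour from blue (lower) to red (higher) with the value printed in each cell; stars mark lists past 5% FDR by camera. The integrated stress response list read 1.59 in spheroids against monolayers and -1.08, -1.12 and -1.49 after 2, 4 and 6 weeks of storage against spheroids.

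The mean of the 3 stored groups, of which 2 lay in the other set, differed from spheroids in 6168 genes (3405 higher, 2763 lower, but 2251 and 2371 with the dimmer 50% of probe sets left out and 2027 and 2385 with the monolayer difference subtracted), of which 900 changed over 2-fold (306 higher, 594 lower). ZNF34 rose by 3.48 (SE 0.10), CCNL1 by 2.46 (SE 0.13), WTAP by 2.38 (SE 0.23), and AFG2B, VCPKMT and RFWD3 by 2.36, 2.33 and 2.32. The log2 changes of GDF15, GRB10, SLIT2, DDIT4, SOX11 and PTPRK were -3.64, -3.59, -3.49, -3.43, -3.27 and -2.95. Among lists, 14 passed (6 upward, 8 downward) and 0 with an estimated correlation. The integrated stress response was lowest, with 18 of 23 genes lower and 2 higher, the same adjusted over the list alone (adjusted p = 2.98e-07, and adjusted p = 0.15 with an estimated correlation), SLC7A1 among them at -2.07 (SE 0.11). The proteasome list had 24 of 30 genes higher and 0 lower, the same adjusted over the list alone (adjusted p = 2.53e-06, and adjusted p = 0.42 with an estimated correlation), PSMD2 among them at 1.10 (SE 0.07).

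At all 3 storage times 1365 genes were higher and 1651 lower than in spheroids, 3016 in all. Lists of these sizes drawn independently would share 223 and 166 genes. In 20 simulations of unchanged groups, 0 genes passed in this way. Few genes pass in any single comparison when none is changed, so this 0 does not bear on overlap among genes that change. The 3 comparisons share the same 3 spheroid arrays, which cannot be split, so part of the excess over independent lists may come from shared controls. A further 180 genes were higher at one time and lower at another.

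**Figure D4:**
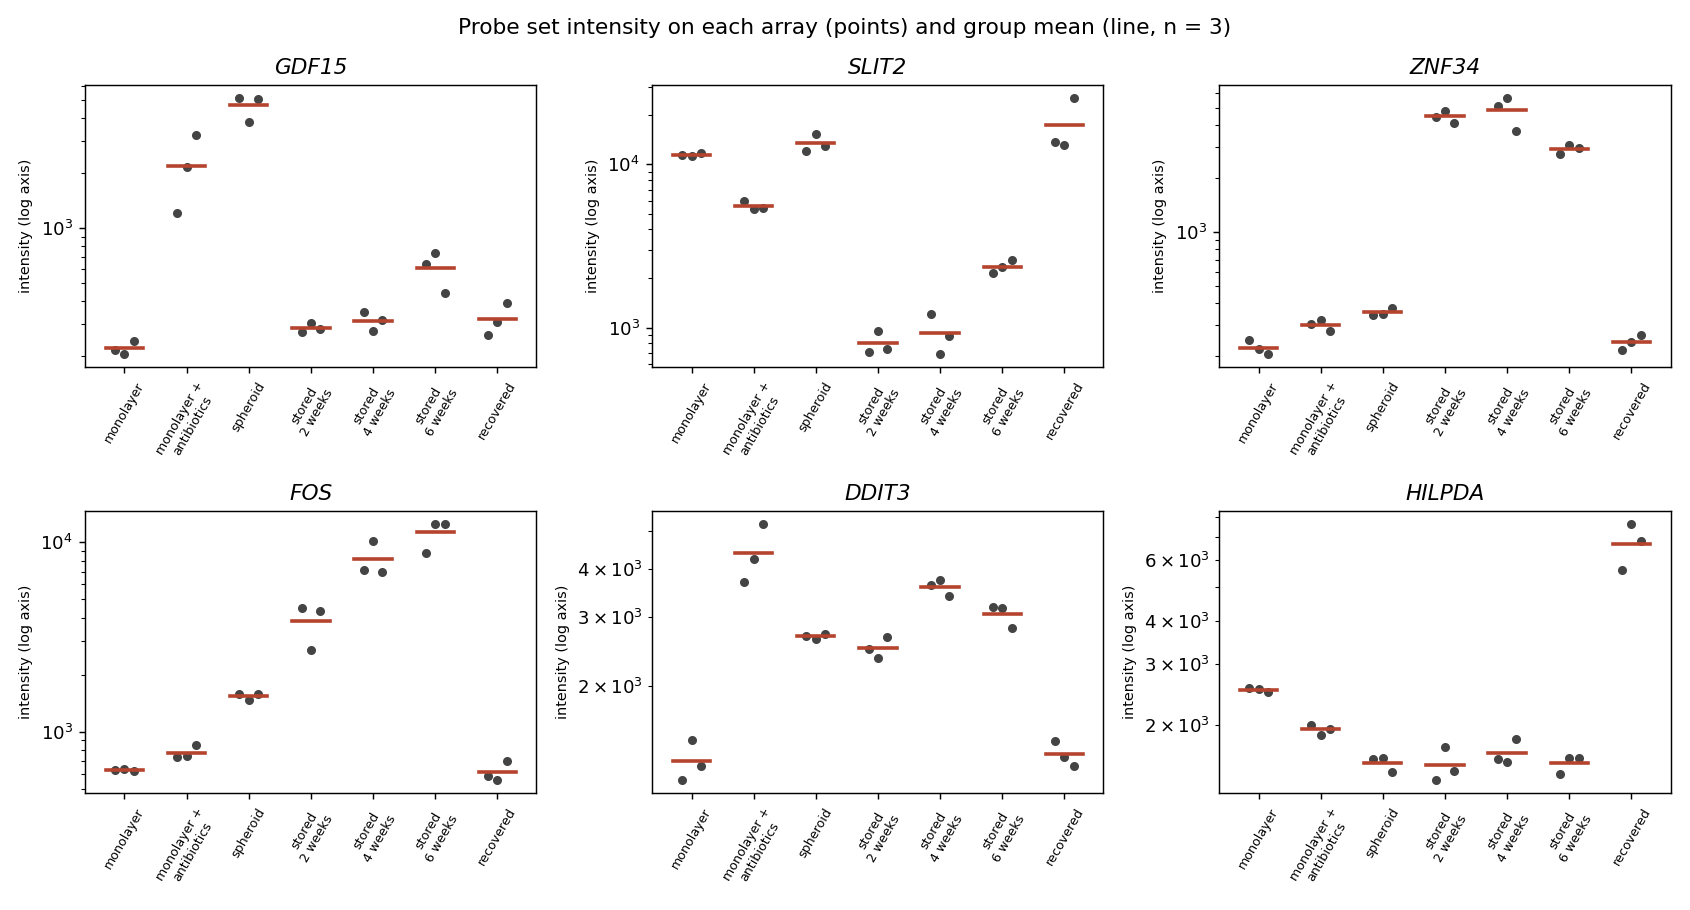
Probe set intensity on log axes for GDF15, SLIT2, ZNF34, FOS, DDIT3 and HILPDA in the 7 groups; points are arrays and lines are means of 3 arrays. ZNF34 read 353.7 in spheroids, 4456, 4818 and 2920 after 2, 4 and 6 weeks, and 240.7 in recovered cells.

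Whether storage length mattered was asked by comparing 6 with 2 weeks, in different hybridisation sets, and the change from 4 to 6 weeks within the second set is given beside it. Both comparisons use the same 6-week arrays, so they are not independent. The 5' 28S control read 1159 ± 145 at 4 weeks and 413.7 ± 258 at 6 weeks, a difference that the change within the set may carry. From 2 to 6 weeks 2983 genes differed (1667 higher, 1316 lower; 1286 and 1612 after centring on the array median), and 273 changed over 2-fold (176 higher, 97 lower). PSPC1 rose from 621.3 ± 218 to 3911 ± 159, 6.54-fold (2.71, SE 0.18, adjusted p = 9.36e-10), and by 2.84 (SE 0.18) within the set. NPTX2 (213479_at), a secreted neuronal protein, rose by 2.60 (1.96 within the set), the co-chaperone DNAJB6 (209015_s_at) by 2.40 (2.30 within the set), and the transcription factor KLF5 by 2.04 (0.85 within the set). CITED2 rose by 2.15 (0.91 within the set) and EIF5B by 2.00 (1.47 within the set), although 1 of 3 other EIF5B probe sets moved the other way. FZD6 (203987_at), a Wnt receptor, changed by -2.27 (-0.87 within the set), NIBAN1 by -2.14 (-1.29 within the set) and TPD52 by -1.85 (-1.29 within the set). COQ2 changed by -1.75 (-0.80 within the set). DTNA and RBM12 changed by -1.67 each (-0.44 and -0.87 within the set), but 1 of 3 other DTNA probe sets and the 1 other RBM12 probe set moved the other way, and RBM12 did not pass with the monolayer difference subtracted (adjusted p = 0.0855). The change of DTNA within the set did not pass without the 4-week replicate 1 or 2 or any single 6-week array, and was -0.288 (adjusted p = 0.182) without the 4-week replicate 2.

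Of 8 lists past 5% FDR between 2 and 6 weeks, 5 were higher and 3 lower, and 0 passed with an estimated correlation. Heat shock genes rose in 10 of 22 and fell in 1 (12 and 1 adjusted over the list alone; median 0.30, adjusted p = 8.84e-05, and adjusted p = 0.207 with an estimated correlation). HSPH1 rose by 1.75 (SE 0.15), DNAJB1 rose by 1.32 (SE 0.12) and HSPD1 rose by 0.66 (SE 0.06). Within the set these genes rose by 1.74, 1.02 and 0.67, and the list had 8 members higher and 0 lower (adjusted p = 3.62e-05, and adjusted p = 0.196 with an estimated correlation). Mitosis genes fell in 23 of 53 and rose in 5 (24 and 6 adjusted over the list alone; adjusted p = 0.000811, and adjusted p = 0.635 with an estimated correlation). CENPN fell by 1.49 (SE 0.17) and TPX2 fell by 1.05 (SE 0.12). Within the set CENPN fell by 0.91, and the list had 23 members lower and 2 higher (adjusted p = 5.8e-06, and adjusted p = 0.67 with an estimated correlation). With the monolayer difference subtracted, however, the mitosis list passed as higher at 6 than at 2 weeks (0.00411), and TPX2 moved to -0.16 and did not pass. Histone genes rose in 11 of 25 and fell in 0, the same adjusted over the list alone (adjusted p = 0.00554, and adjusted p = 0.44 with an estimated correlation). H2BC5 rose by 1.25 (SE 0.18) and H2AX rose by 0.70 (SE 0.06). Within the set the histone list did not pass (median 0.06, adjusted p = 0.44), with 5 members higher and 0 lower. Targets of p53 rose in 10 of 22 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.00554, and adjusted p = 0.374 with an estimated correlation). SESN1 rose by 0.66 (SE 0.12) and AEN rose by 0.63 (SE 0.11). The p53 list did not pass within the set (median 0.12, adjusted p = 0.11), with 5 members higher and 0 lower, nor with the monolayer difference subtracted (0.466), where SESN1 and AEN moved to 0.185 and 0.342 and did not pass. The calls of the other 4 lists ended without single arrays: oxidative phosphorylation without the 6-week replicate 3 (0.0962), DNA replication without the 2-week replicate 2 or 6-week replicate 3 (up to 0.059), cyclin-dependent kinase inhibitors without the 2-week replicate 3 or 6-week replicate 2 or 3 (up to 0.101), and actin genes without the 6-week replicate 1 or 2 (up to 0.0845). Within the set actin genes passed as higher (adjusted p = 0.00157, at most 0.00693 with an array left out, and 0.271 with an estimated correlation). Oxidative phosphorylation passed there as lower (0.00109), but not without the 6-week replicate 3 (0.0953) nor with an estimated correlation (0.748). Kinase inhibitors (median 0.173, adjusted p = 0.073) and DNA replication, whose median turned to 0.044 (adjusted p = 0.0757), did not pass there. RFC3 of the replication list fell by 1.28 (SE 0.13) from 2 to 6 weeks, and its change within the set was -0.12 (adjusted p = 0.573).

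Recovered cells were compared with unstored monolayers to ask how far the cells had returned to the unstored state. The planned control, the monolayer with antibiotics, lay in the other hybridisation set, so values against the monolayer without antibiotics, within the set, stand beside it. Rehydration was in medium with 20% serum, and no serum level is known here for the monolayers, so serum may differ in both comparisons. Against the planned control 2910 genes differed (1165 higher, 1745 lower; 1482 and 1211 after centring on the array median) and 132 over 2-fold (61 higher, 71 lower). Against the control in the same set 1406 differed (565 higher, 841 lower, but 645 and 621 after quantile normalization) and 49 over 2-fold (36 higher, 13 lower). Without recovered replicate 3 the second count fell to 707, and without monolayer replicate 1 or 3 it was 847 or 871. TXNIP (201010_s_at), an inhibitor of thioredoxin, read 7354 ± 5240 against 900.7 ± 55.1 in the planned control (2.81, SE 0.29, adjusted p = 3.04e-07) and 2.51 higher within the set. Its 3 recovered arrays read 4670, 3996 and 13397. The chemokine receptor CXCR4 (211919_s_at) rose by 2.19 (0.85 within the set), NDRG1 (200632_s_at), a hypoxia-induced gene, by 1.84 (0.93 within the set, but 0.57 with adjusted p = 0.0755 without recovered replicate 3) and HILPDA (218507_at), a hypoxia-induced lipid droplet protein, by 1.77 (1.39 within the set). ASXL2 and H1-2 rose by 1.97 and 1.78 against the planned control and differed by -0.19 and -0.05 within the set. Against the planned control GDF15, NUPR1, CRELD1 and NIBAN1 changed by -2.70, -2.37, -2.27 and -2.05, but within the set they differed by 0.51, 0.06, 0.35 and 0.27. TRIB3 and SDF2L1 changed by -2.23 and -1.99, and by -0.24 and -0.63 within the set. There TRIB3 did not pass, nor did SDF2L1 without recovered replicate 3 (0.174), monolayer replicate 1 (0.0813) or monolayer replicate 3 (0.061).

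Lists past 5% FDR against the planned control numbered 10 (6 upward, 4 downward). Hypoxia response genes rose in 14 of 28 and fell in 2 (16 and 2 adjusted over the list alone; median 0.41, adjusted p = 6.46e-09). BNIP3 rose by 1.63 (SE 0.16) and PDK1 rose by 1.04 (SE 0.12), and within the set BNIP3 differed by 0.47 without passing and PDK1 rose by 1.07. Of the list within the set 12 rose and 0 fell (16 and 1 adjusted over the list alone; median 0.44, adjusted p = 2.61e-10), and the list passed with an estimated correlation against both controls (0.0305 and 0.0233). Glycolysis genes rose in 12 of 17 and fell in 0, the same adjusted over the list alone (adjusted p = 6.33e-07, and adjusted p = 0.0825 with an estimated correlation). PGK1 rose by 1.15 (SE 0.12) and LDHA rose by 0.78 (SE 0.11), to means of 37240 and 36200, not far under the ceiling. Within the set PGK1 rose by 0.54, and LDHA differed by 0.07 (adjusted p = 0.776). In glycolysis within the set 4 genes rose and 0 fell (adjusted p = 0.00326, and adjusted p = 0.256 with an estimated correlation). The integrated stress response list had 21 of 23 genes lower and 1 higher (22 and 1 adjusted over the list alone; median -1.04, adjusted p = 1.77e-16). DDIT3 fell by 1.71 (SE 0.12) and SLC3A2 fell by 1.54 (SE 0.12). The unfolded protein response had 16 of 20 lower and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 1.89e-14). MANF fell by 1.60 (SE 0.12) and CRELD2 fell by 1.26 (SE 0.10). Both passed with an estimated correlation (0.00772 each). Within the set neither passed, with medians of 0.02 each and adjusted p of 0.924 and 1, and DDIT3 and MANF differed by 0.06 and -0.23 without passing. The changes of SLC3A2 and CRELD2 there were -0.38 and -0.34.

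Mitosis genes rose against the planned control in 36 of 53 and fell in 0 (41 and 0 adjusted over the list alone; median 0.52, adjusted p = 9.33e-19), passed with an estimated correlation (0.0313), and included BUB1 (1.41, SE 0.14), TPX2 (1.07, SE 0.12) and securin, PTTG1 (0.76, SE 0.08). Within the set 3 rose, the median was -0.04 and the list did not pass (adjusted p = 0.74). BUB1 and TPX2 then differed by 0.20 and 0.17 and did not pass, and PTTG1 rose by 0.31. Interferon response genes fell in 15 of 27 and rose in 0 (17 and 0 adjusted over the list alone; adjusted p = 0.00015) and passed with an estimated correlation (0.0216). IFI16 fell by 2.02 (SE 0.17) and IFI35 fell by 0.84 (SE 0.08). Within the set 5 of these genes rose and 2 fell (7 and 3 adjusted over the list alone; median 0.05), and the list, then higher, did not pass (adjusted p = 0.0512, and adjusted p = 0.154 with an estimated correlation). IFI16, with 2 of 3 monolayer arrays at the floor, differed by at least 0.49 there and did not pass, and IFI35 changed by -0.33. Cytosolic tRNA synthetases fell in 9 of 16 and rose in 0, the same adjusted over the list alone (adjusted p = 0.000143, and adjusted p = 0.0543 with an estimated correlation), and within the set 4 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.00777, but 0.149 with an estimated correlation and 0.0517 after quantile normalization). Heat shock genes rose in 10 of 22 and fell in 2, the same adjusted over the list alone (adjusted p = 0.00198, and adjusted p = 0.133 with an estimated correlation). CHORDC1 rose by 1.43 (SE 0.15). Within the set 8 heat shock genes fell and 1 rose, and CHORDC1 differed by -0.91. Calls of 2 further lists ended without single arrays: oxidative phosphorylation without recovered replicate 2 or antibiotic monolayer replicate 3 (up to 0.204), and splicing factors without recovered replicate 1 or 2 or antibiotic monolayer replicate 3 (up to 0.145). Within the set splicing factors passed the other way, as lower (adjusted p = 7.76e-05, and adjusted p = 0.11 with an estimated correlation). Without antibiotic monolayer replicate 2 the count of genes was 1904.

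Of 1190 genes that differed over 2-fold between cells stored for 2 weeks and monolayers without antibiotics, 268 passed and 21 differed over 2-fold between recovered cells and those monolayers, where 1406 of all 9844 genes passed. Both comparisons use the same 3 monolayer arrays. Against both monolayer groups 371 genes differed in the same direction (177 higher, 194 lower), and 9 of them over 2-fold in both. Independent lists would share 216, but both comparisons use the same 3 recovered arrays, so the excess may come from shared arrays.

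Recovered cells were compared with cells stored for 2 weeks, within the first set, to ask what 72 hours of attached culture changed, and medium with 20% serum, antibiotics and attachment changed along with rehydration. The comparison gave 4988 genes (2629 higher, 2359 lower, but 2517 and 2646 after centring on the array median), 1299 of them over 2-fold (715 higher, 584 lower). IGFBP5 (211959_at), which binds insulin-like growth factors, rose from 292.7 ± 27.3 to 10550 ± 3450, 35-fold (5.13, SE 0.26, adjusted p = 6.65e-13). SLIT2 rose by 4.39 (SE 0.20) to 17460 ± 7080, IRS4 (207403_at), an adaptor of insulin signalling, by 3.44 (SE 0.21), adducin 3, ADD3, by 3.35 (SE 0.20), the glucocorticoid-induced TSC22D3 by 3.26 (SE 0.21) and the matrix proteoglycan VCAN by 3.02 (SE 0.29). ZNF34 fell by 4.21 (SE 0.13) to 240.7 ± 23, and GADD45B fell by 3.61 (SE 0.16). The tachykinin precursor TAC1, SNHG17, PPP1R15A and OSER1 changed by -3.09, -3.06, -2.96 and -2.82, with 1 recovered array at the floor for TAC1.

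Of 12 lists past 5% FDR after recovery, 7 were higher and 5 lower, and 0 passed with an estimated correlation. Glycolysis genes rose in 14 of 17 and fell in 0, the same adjusted over the list alone (median 0.99, adjusted p = 5.23e-07, and adjusted p = 0.176 with an estimated correlation). GPI rose by 2.12 (SE 0.14), PGK1 rose by 1.55 (SE 0.12), to the same mean not far under the ceiling, and HK1 rose by 1.37 (SE 0.10). Extracellular matrix genes rose in 24 of 41 and fell in 1, the same adjusted over the list alone (adjusted p = 1.05e-05, and adjusted p = 0.211 with an estimated correlation). LAMC1 rose by 2.47 (SE 0.17) and COL4A5 rose by 2.40 (SE 0.15). Fatty acid synthesis genes rose in 10 of 11 and fell in 0, the same adjusted over the list alone (adjusted p = 3.21e-05, and adjusted p = 0.176 with an estimated correlation). SCD rose by 1.86 (SE 0.10) and ELOVL6 rose by 1.70 (SE 0.13). Hypoxia response genes rose in 19 of 28 and fell in 4, the same adjusted over the list alone (adjusted p = 0.000536, and adjusted p = 0.211 with an estimated correlation). DDIT4 rose by 2.71 (SE 0.16) and P4HA2 rose by 1.96 (SE 0.18). Actin and SRF target genes rose in 14 of 31 and fell in 0, the same adjusted over the list alone (adjusted p = 0.000983, and adjusted p = 0.176 with an estimated correlation). Antioxidant enzymes rose in 11 of 18 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.00478, and adjusted p = 0.226 with an estimated correlation). MSRB2 rose by 1.96 (SE 0.13).

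Immediate early genes fell after recovery in 17 of 30 and rose in 1 (19 and 1 adjusted over the list alone; adjusted p = 1.05e-05, and adjusted p = 0.226 with an estimated correlation). EGR1 fell by 2.41 (SE 0.14) and IER2 fell by 1.67 (SE 0.10). Targets of NF-kappaB fell in 11 of 24 and rose in 0, the same adjusted over the list alone (adjusted p = 0.00617, and adjusted p = 0.176 with an estimated correlation). CXCL8 fell by 2.78 (SE 0.20) and TNFAIP3 fell by 1.88 (SE 0.16). Proteasome genes fell in 20 of 30 and rose in 1, the same adjusted over the list alone (adjusted p = 0.000174, and adjusted p = 0.423 with an estimated correlation). PSMC2 fell by 1.21 (SE 0.10) and PSMB7 fell by 1.02 (SE 0.10). Splicing factors fell in 27 of 42 and rose in 5 (27 and 6 adjusted over the list alone; adjusted p = 0.000429, and adjusted p = 0.211 with an estimated correlation). The kinase CLK1, with 1 recovered array at the floor, fell by 2.61 (SE 0.16), and SF3A1 fell by 1.69 (SE 0.11). Nucleolar genes fell in 16 of 30 and rose in 5, the same adjusted over the list alone (adjusted p = 0.0306, and adjusted p = 0.594 with an estimated correlation). RRN3 fell by 2.21 (SE 0.17). The nucleolar list did not pass without the 2-week replicate 2 or recovered replicate 3 (up to 0.0886) or after quantile normalization (0.0673). Cholesterol synthesis genes rose in 9 of 19 and fell in 1, the same adjusted over the list alone (adjusted p = 0.0348, and adjusted p = 0.211 with an estimated correlation), but did not pass without recovered replicate 2 (0.0559).

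The 2 unstored monolayer groups differ by label in antibiotics alone, but each lay in its own hybridisation set, so antibiotics and set cannot be told apart. They differed in 3817 genes (2080 higher with antibiotics, 1737 lower; 1416 and 2183 after centring on the array median, 1403 and 1567 with the dimmer 50% of probe sets left out), of which 255 changed over 2-fold (128 higher, 127 lower). GDF15 read 2201 ± 1020 against 221.7 ± 19.4 (3.20, SE 0.24, adjusted p = 2.43e-09), CRELD1 (203368_at) rose by 2.63 (SE 0.14), the arginine synthesis enzyme ASS1 (207076_s_at) by 2.52 (SE 0.24), NUPR1 by 2.43 (SE 0.18), the growth factor midkine, MDK, by 2.33 (SE 0.20) and NIBAN1 by 2.32 (SE 0.16). CHORDC1 (218566_s_at), a co-chaperone, changed by -2.33 (SE 0.15), and INSIG1 and SQLE, genes of sterol homeostasis, by -2.27 (SE 0.15) and -2.12 (SE 0.15). The changes of ASXL2, HMGN5 and the RNA-processing enzyme DICER1 were -2.16, -1.92 and -1.88.

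Between the monolayer groups 17 lists passed, 7 upward and 10 downward. The integrated stress response rose in 22 of 23 genes and fell in 1, the same adjusted over the list alone (median 1.01, adjusted p = 2.02e-13). DDIT3 rose by 1.77 (SE 0.12) and ATF4 rose by 1.09 (SE 0.09), to a mean of 35020. The unfolded protein response rose in 15 of 20 and fell in 0 (17 and 0 adjusted over the list alone; median 1.14, adjusted p = 1.39e-11). PDIA4 rose by 1.58 (SE 0.12) and calreticulin, CALR, rose by 1.46 (SE 0.10). Interferon response genes rose in 21 of 27 and fell in 1 (23 and 2 adjusted over the list alone; adjusted p = 1.1e-06). IFITM3 rose by 0.99 (SE 0.10). IFI16 rose to 950.7 ± 342 from 142.7 ± 17.2 (2.52, SE 0.17), where 2 of 3 arrays were at the floor, so its fold is a lower bound. Targets of p53 rose in 12 of 22 and fell in 1, the same adjusted over the list alone (adjusted p = 0.000384). CDKN1A rose 2.82-fold and DDB2 2.08-fold. Heat shock genes fell in 16 of 22 and rose in 2, the same adjusted over the list alone (adjusted p = 2.75e-07). HSPH1 fell by 1.58 (SE 0.15) and DNAJA1 fell by 0.84 (SE 0.08). Cholesterol synthesis genes fell in 11 of 19 and rose in 2, the same adjusted over the list alone (adjusted p = 3.47e-05). ACAT2 fell by 1.60 (SE 0.11). With an estimated correlation these lists passed at 0.0134, 0.0134, 0.0103, 0.0488, 0.014 and 0.014 in that order, and fibroblast markers at 0.0217.

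Mitosis genes fell with antibiotics in 35 of 53 and rose in 0, the same adjusted over the list alone (adjusted p = 3.15e-13, and adjusted p = 0.0587 with an estimated correlation). BUB1 fell by 1.20 (SE 0.14) and AURKA fell by 1.06 (SE 0.12). Extracellular matrix genes rose in 22 of 41 and fell in 0, the same adjusted over the list alone (adjusted p = 1.8e-06, and adjusted p = 0.117 with an estimated correlation). SPARC rose 2.83-fold (SE 0.14 on the log2 scale) and the collagen chain COL4A2 rose by 1.45 (SE 0.17). The list of 11 fibroblast markers had 5 members higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 0.00227). Oxidative phosphorylation and glycolysis did not pass after quantile normalization (0.134 and 0.0544), nor histones without monolayer replicate 2 (0.074).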

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

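Chosen after the results were seen were the comparison of 6 with 4 weeks and the tests of antibiotics alone, of transcript decay, of ribosomal RNA signal and of non-specific signal. The test of the hybridisation set was written before its result was seen.

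Results here were singled out because storage times differed in a direct test, or because a signal appeared in control probe sets that no comparison used. Between 6 and 2 weeks 2983 genes passed 5% FDR, and between 6 and 4 weeks, within the second hybridisation set, 1988 passed (1268 higher, 720 lower). From 4 to 6 weeks the median change of heat shock genes was 0.252 and that of mitosis genes -0.315. The 5' control for 28S ribosomal RNA read 468, 1159 and 413.7 on average after 2, 4 and 6 weeks against 229.7 in spheroids. The lowest BioB reading in the second hybridisation set was 823, above the 747 that was highest in the first.

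The monolayers grown with antibiotics differed from those grown without in 3817 genes, including higher integrated stress and unfolded protein response genes (median 1.02 over 43 genes). If the hybridisation set were the cause, the stress genes would also differ between 4 and 2 weeks of storage, across the same sets, and their median there was 0.051 (95% interval -0.062 to 0.158). If antibiotics alone were the cause, recovered cells, whose medium held antibiotics, would differ from monolayers without them, and that median was 0.023 (95% interval -0.118 to 0.094). Both intervals come from resampling genes and leave out the spread between arrays. The recovered cells had also been stored and may differ in serum, either of which could offset an effect of antibiotics. Over all genes past 5% FDR, the monolayer difference correlated across genes with the 4-week minus 2-week difference at r = 0.375, between the values expected with the set as the cause (above 0.5) and without it (below 0.1), and genes are not independent replicates. Over all genes the set cannot be told apart from antibiotics, and a difference in density or state between cultures grown on other days was not tested.

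The mean of the 3 stored groups, of which 2 lay in the other set, differed from spheroids in 6168 genes, and in 4412 with the monolayer difference subtracted. If transcripts had only decayed without new synthesis, labile immediate early transcripts would be lower. In the mean of stored groups 16 of 30 were higher and 3 lower (adjusted p = 0.0212, but 0.583 with an estimated correlation and 0.0514 with the monolayer difference subtracted). At 2 weeks, within the set of the spheroids, 14 were higher and 5 lower and the list did not pass (adjusted p = 0.111). Decay alone and a response of the cells therefore cannot be told apart, as the members are regulated together and their lability in stored cells was not measured. Values are relative to the other transcripts of an array, so a rise shows unequal loss or synthesis and not an absolute gain. Ribosomal RNA signal stays open as a source of the 6-week changes. Without replicate 1, which read highest (711), 4753 genes passed, against 5204. The other arrays (272 and 258) also read above every spheroid array (225 to 236) on the 5' probe set, and on the middle one (2462 and 2630 against 1751 to 1838). On the 3' 28S probe set they did not (305 and 250 against 278 to 350). Unstored antibiotic monolayers of the same hybridisation set read 231 to 280 on the 5' probe set. Whether the signal was removed depends on the probe set and the reference, so the test cannot decide. A response of the cells during the first days of storage is a candidate explanation that the design, which has no earlier time, did not test.

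Small rises of dim genes were frequent at 4 weeks, where 1113 of 2461 genes in the dimmest group passed as higher and 320 as lower. If non-specific signal had risen, Bacillus control probe sets would have risen as well, and the median of 27 of them was 0.129 higher (95% interval 0.055 to 0.195, from resampling probe sets and not arrays), against 0.197 for the dimmest genes. A raised background may thus account for part of these rises. The leukocyte markers rose by more, a median of 0.429, above the interval of the control probe sets, and whether background contributed to their rise stays open. Over 2-fold, 28 of the dimmest genes were higher and 59 lower. No biological explanation was tested.

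Relabelling arrays tested whether groupings other than the real one gave as many genes. For the mean of the 3 stored groups, 1 of 100 splits drawn, the real one, gave as many as 6168 genes, and the highest other gave 1312. The other splits also mixed the storage times at random, which widens their residual spread. The result therefore shows only that single arrays were not interchangeable. With whole groups as units the real split is 1 of 4, so chance at that level cannot be excluded. For comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. There too, splits that mix the groups widen the spread. The highest other split gave 0 genes against the real 3058, 4632, 6259, 5204, 2983, 4988 and 3817 for spheroids against monolayers, the 3 storage times against spheroids, 6 against 2 weeks, recovered against 2 weeks and the monolayer groups. It gave 3 against 2910 for recovered cells and the planned control, 1 against 1406 for recovered cells and monolayers without antibiotics, and 1 against 1988 for 6 and 4 weeks.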

How the results depend on the processing

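The subtraction of the monolayer difference, the mean of the stored groups without the 4-week arrays, the settings at the level of single lists, the control without antibiotics for lists and as a comparison of its own, the comparison of 6 with 4 weeks, and the overlap with arrays left out were chosen after the data were seen. The others were fixed before.

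Of 2862 recomputed values of the genes named, without leaving out arrays, 2838 kept their direction and side of the threshold, 14 no longer passed and 10 changed sign. This total pools settings that hardly alter a value, such as other floors, with the other control for recovered cells. It therefore understates how far the recovered comparison depends on its control. With that control TRIB3, BUB1, TPX2, MANF, BNIP3, LDHA and SARS1 no longer passed. With 1 array left out, 1566 of 1566 kept both. The named genes were picked from these same arrays for groups that did not overlap or for the smallest p, so this count is no independent support. The values that changed sign when recovered cells were set against monolayers without antibiotics were those of ASXL2 (-0.191), H1-2 (-0.052), GDF15 (0.505), NUPR1 (0.057), CRELD1 (0.353), NIBAN1 (0.273), DDIT3 (0.061), IFI16 (0.494, with 2 of 3 monolayer arrays at the floor) and CHORDC1 (-0.906). SCD at 6 weeks moved to 0.054 with the monolayer difference subtracted. The cause was not tested, beyond what is said of the monolayer groups. In the 2 comparisons chosen after the data were seen, 596 of 611 values of named genes kept both, and 15, of NDRG1 and SDF2L1 in recovered cells and of DTNA and RBM12 between 6 and 4 weeks, no longer passed. With the mean of a gene's probe sets, DTNA moved to -0.061 and RBM12 to -0.429.

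Counts of genes in the comparisons stayed within 1.5 times the value reported, except as follows. For recovered cells against monolayers with antibiotics, 2910 genes became 1860 with the compared groups alone. They became 1406 against monolayers without antibiotics and 1359 against the mean of both monolayers. With each array left out they ranged from 1904 (without antibiotic monolayer replicate 2) to 2742 (without antibiotic monolayer replicate 1). The compared groups alone raised other counts, as from 3058 to 3670 for spheroids against monolayers, and the cause was not tested. After 4 weeks, 6259 genes became 4035 (1801 higher, 2234 lower) with the monolayer difference subtracted, which adds the error of 6 arrays. Recovered cells against monolayers without antibiotics gave 596 genes with the compared groups alone. With each array left out this count ranged from 707 (without recovered replicate 3) to 1658 (without recovered replicate 2). Genes changed at all 3 storage times, 3016, ranged from 2604 to 2979 with arrays left out and were 2198 at 1% FDR and 3111 after quantile normalization.

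With an estimated correlation, lists passed in 3 cases for spheroids against monolayers, 5 for recovered cells against monolayers with antibiotics and 7 between the monolayer groups, and in 0 cases in the other 6 comparisons. In those 6, limma's camera gave 6, 5, 6, 6, 3 and 8 lists at an unadjusted p under 0.05 at 2, 4 and 6 weeks, in the mean of stored groups, for 6 against 2 weeks and after recovery. Limma's fry, which tests whether a list's genes move one way and does not compare them with other genes, passed 29, 31, 30 and 31 lists at 2, 4 and 6 weeks and in their mean, 17 for recovered cells against monolayers with antibiotics and 29 against 2 weeks. Against monolayers without antibiotics, 17 lists passed for recovered cells by camera with the fixed correlation, and 4 with an estimated one. Between 6 and 4 weeks 0 lists passed with an estimated correlation and 13 with fry. Between 6 and 2 weeks, 15 lists passed with the monolayer difference subtracted, and from 5 (without the 6-week replicate 3) to 10 (without the 2-week replicate 2) with an array left out. With the subtraction the median of the integrated stress response moved from -0.208 to -1.214 (camera adjusted p = 4.7e-14). That of the unfolded protein response moved from -0.012 to -0.876 (1.31e-10), and that of cholesterol synthesis from 0.116 to 0.464 (8.29e-05). The cause was not tested.

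Replicate numbers gave no general pairing of the arrays: over 63 pairs of arrays with the same number the median correlation of residuals was -0.002. It was 0.011 for different numbers. Among the 63 pairs the correlation ranged from -0.263 to 0.431, and 15 pairs lay above 0.1, so pairing between some groups cannot be excluded. With the number as a block, 3044, 4635, 6225, 5192, 6139, 2964, 2846, 4963 and 3768 genes passed, in the order of the report. Signal limited dim genes, as 8.59% to 11.1% of probe sets per array were at the floor, and bright genes, as 75 were near the ceiling.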

Other observations

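The comparison of recovered cells with monolayers grown without antibiotics, its genes and its lists were chosen after the data were seen.

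Cells that had recovered for 72 hours had more matrix transcripts than unstored monolayers of the same hybridisation set, which were grown without antibiotics. Against the planned control the matrix list did not pass by camera (median -0.041, adjusted p = 0.393). Integrins did not pass there either (median -0.004, adjusted p = 0.527). Matrix genes were also higher in monolayers with antibiotics than without. Recovered cells were rehydrated in medium with 20% serum, and no serum level is known here for the monolayers. Antibiotics, a difference in serum and recovery therefore cannot be told apart here. Within the set, 20 of 41 measured extracellular matrix genes rose and 0 fell (23 and 0 adjusted over the list alone, median 0.35, adjusted p = 3.16e-16). The list passed there with an estimated correlation (0.0233). Fibronectin, FN1, rose by 1.37, LOXL1, a lysyl oxidase that cross-links elastin, by 1.33, the collagen chain COL4A2 by 1.28 and the protease inhibitor TIMP1 by 0.92. IGFBP5 rose by 1.83. Integrins and genes of adhesion to substrate rose in 7 of 25 and fell in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.000374, and adjusted p = 0.094 with an estimated correlation). ITGA6 rose by 0.51. Fibroblast markers rose in 2 of 11 and fell in 0, the same adjusted over the list alone (adjusted p = 0.023, and adjusted p = 0.094 with an estimated correlation), but did not pass after quantile normalization (0.0674). Recovered replicate 3 stood apart in some of these genes, with FN1 at 8752 against 4568 and 3753 in the other recovered arrays. FN1 read 1800 to 2231 in monolayers without antibiotics and 4105 to 4478 in monolayers with them. Without recovered replicate 3, 707 genes passed within the set, against 1406.

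Lower in recovered cells than in monolayers without antibiotics were genes of cholesterol synthesis, ribosome biogenesis, the proteasome and heat shock. Of these, ribosome biogenesis and the proteasome did not pass with an estimated correlation. Against the planned control none passed as lower by camera. Cholesterol synthesis (median -0.035, adjusted p = 0.146), ribosome biogenesis (-0.1, 0.472) and proteasome genes (0.053, 0.275) did not pass there, and heat shock genes passed as higher (0.166, 0.00198). Cholesterol synthesis and heat shock genes were also lower in monolayers with antibiotics than without. Serum may differ as well, and neither antibiotics nor serum was tested apart from recovery. Within the set cholesterol synthesis genes fell in 11 of 19 and rose in 0 (12 and 0 adjusted over the list alone, median -0.48, adjusted p = 4.88e-07). They passed with an estimated correlation (0.013). ACAT2 fell by 1.45, and IDI1 fell by 0.75. Nucleolar genes of ribosome biogenesis fell in 16 of 30 and rose in 0 (22 and 0 adjusted over the list alone; adjusted p = 1.71e-10, and adjusted p = 0.0723 with an estimated correlation). GAR1 and NOP16 changed by -0.80 each. Proteasome genes fell in 17 of 30 and rose in 0 (20 and 0 adjusted over the list alone; adjusted p = 1.71e-10, and adjusted p = 0.134 with an estimated correlation), with PSMC2 at -0.55. Heat shock genes fell in 8 of 22 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 8.63e-06) and passed with an estimated correlation (0.0447). HSPH1 and DNAJA1 changed by -1.07 and -0.71. ZNF34 and SLIT2, which had the largest rise and the largest fall past 5% FDR at 2 weeks, differed from monolayers without antibiotics by 0.10 (adjusted p = 0.691) and 0.53 (adjusted p = 0.0822). Recovery was measured after 2 weeks of storage and not after 4 or 6.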
